A study of Drosophila melanogaster with 3 samples.

How the data were processed

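Chromatin from asynchronous S2-DRSC cultures was cross-linked and immunoprecipitated with a mouse monoclonal antibody raised against purified yeast MCM complex, which recognises the Walker B motif of the MCM2-7 subunits, per the labels. Libraries were size-selected and sequenced single-end on an Illumina Genome Analyzer II, per the labels' protocols. The 3 samples were grouped from their labels as 2 MCM immunoprecipitations and 1 input. Peaks were called with PeakSeq and placed on FlyBase release 5.1, per the file headers and the caller column of the files. The PeakSeq version and settings, the aligner, the control used for each list and the score threshold are not given in the sources used here. The score in column 6 of each list is the authors' own value per peak, deposited without a named unit. It was used to describe, rank and filter peaks. Comparing it between the replicate lists assumes that both are on the same scale. The authors called peaks per sample, and the series list joined overlapping peaks of both samples, as tested on the positions. Sequencing depth is unknown, so no interval that needs it is given, and binomial intervals are exact (Clopper-Pearson) and cover counting error only.

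Peaks shared at least 1 bp to count as overlapping, and each replicate 1 peak was paired with its largest overlap for scores. Chance overlap came from 100000 circular rotations with a separate offset per chromosome. Chromosome lengths were taken as the last peak end over the 3 lists, and densities per Mb use these lengths. X and autosome densities were compared by permuting 500 kb windows, scores on X by permuting chromosome labels of peaks, and clustering by 10000 uniform placements. Tests were two-sided with a threshold of 0.05, and Benjamini-Hochberg adjustment covered the 8 planned tests. Alternatives fixed before the data were examined were an overlap of at least 50% of a peak's length, centres within 500 bp, the higher-scoring 50% of each list, uniform placement as chance, the major arms alone, each replicate alone, windows of 200 kb and 1 Mb, covered bases, distances of 5 and 20 kb, and merging of peaks closer than 1 kb. Alternatives chosen after seeing the data were quartiles by width, log2 scores, pairs with scores at or below 20, chromosome 4 scores, density near centromeres, the share of matched peaks on X, wide-peak regions and X density without dense windows.

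Regions were named by a rule fixed before the data were examined: the 20 series intervals with the highest score found in both replicates, the 5 widest intervals, the 5 longest stretches without a peak on the major arms, and members of fixed gene lists. The gene annotation in hand was of Release 6, a different build, so no gene coordinate or name was used. The 4 planned tests that need genes or sequence (transcription start sites, genomic features, gene groups over 14 lists, and base composition) were not run. No test across samples was run.

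The code was tested on simulated data. Unrelated lists of the replicate sizes gave p under 0.05 in 1 of 20 runs. Of 9534 simulated sites of which 60% were copied with a shift of position, 56.9% were found. An X density made 1.5 times higher was recovered as 1.50, and an even density gave 0 of 20 runs under 0.05. Uniform placement gave 59.5% of peaks within 10 kb against 59.9% by chance. A correlation made with r = 0.5 was recovered as 0.518. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Numba 0.67.0 and matplotlib 3.10.9.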

Results

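Chromatin occupancy by the MCM2-7 complex, the replicative helicase that is loaded at origins of DNA replication, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in Drosophila melanogaster S2-DRSC cells. S2-DRSC is a male, embryo-derived cell line, and the cultures were asynchronous, so the peaks average over the cell cycle. The 3 samples comprised 2 MCM immunoprecipitations, called replicate 1 and replicate 2 here, and 1 input DNA sample, for which no peak list was analysed here. The labels do not say whether the replicates came from separate cultures, so the spread between them may be technical. The values are peak positions and a score per peak given by the authors. Read counts were not used here and sequencing depth is therefore unknown, which leaves the difference in peak number between the replicates without a depth to set it against.

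MCM peaks were numerous and narrow, and most lay on the major chromosome arms 2L, 2R, 3L, 3R and X. Replicate 1 had 9668 peaks with a median width of 133 bp (interquartile range 73 to 232 bp), covering 1914213 bp. Replicate 2 had 8447 peaks with a median width of 97 bp (44 to 179 bp), covering 1294929 bp. Peaks under 50 bp made up 16.9% of the replicate 1 list and 27.7% of the replicate 2 list, and the shortest in each was 1 bp wide. Widths are therefore those of the called intervals and need not be the extent of MCM binding. The list of the whole series had 5726 intervals with a median width of 206 bp (141 to 330 bp), covering 1745128 bp, and 98.0% of them were on the major arms. Each of the 5726 intervals spanned exactly the overlapping peaks of both replicates. In the 5486 intervals with 1 peak from each replicate, the score was the mean of both replicate scores to within 1e-04. The series list is therefore treated below as the peaks found in both replicates, with each interval running over the joined extent of its overlapping peaks. Its widths and covered length thus include sequence called in only 1 replicate.

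The first comparison asked whether MCM was found at the same positions in both immunoprecipitations. Of the replicate 1 peaks, 5784 (59.8%, exact 95% interval 58.8 to 60.8) overlapped a replicate 2 peak by at least 1 bp. Of the replicate 2 peaks, 5935 (70.3%, 69.3 to 71.2) overlapped a replicate 1 peak. Rotating one list along each chromosome gave 2.16% ± 0.193 (SD over 100000 rotations) and 2.49% ± 0.221, so the observed shares were 27.7 and 28.2 times the chance value. Both were beyond chance in a two-sided permutation test by rotation (p = 1e-05, the smallest that the rotations can give; adjusted p = 1.6e-05 over 8 tests). Peaks are not independent replicates, and the test compares positions in these 2 libraries. The labels list 1 input sample, and which control was used for each list is not given in the sources used here. Overlap that comes from a common control can therefore not be told apart from overlap of MCM signal.

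Overlap varied among chromosomes. On the major arms, 59.2% (X) to 62.7% (3R) of replicate 1 peaks were found in replicate 2. Replicate 2 peaks were found in replicate 1 in 81.4% of cases on 2L, 77.8% on 2R, 76.0% on 3R, 71.5% on 3L and 65.5% on X. On the small chromosome 4, the shares were 37.4% of 123 peaks in replicate 1 and 55.6% of 90 peaks in replicate 2. On the heterochromatin scaffolds they were 36.4% of 140 peaks and 23.4% of 218 peaks. On the unplaced sequence U, 18 of 54 replicate 1 peaks (33.3%) and 18 of 291 replicate 2 peaks (6.19%) were shared.

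Peaks that were shared had similar scores in both replicates. Across 5784 pairs of overlapping peaks, Spearman's rho was 0.776 and Pearson's r was 0.596 (permutation p = 1e-05 for each, the smallest that 100000 pairings can give; adjusted p = 1.6e-05 for rho). Within chromosome arms rho lay between 0.753 (X) and 0.803 (3L), and it was 0.718 over the 46 pairs on chromosome 4. The median log2 ratio of replicate 2 over replicate 1 was 0.03, with an interquartile range from -0.19 to 0.25. Replicate 1 peaks were the wider member in 4549 pairs (78.6%), with median widths of 191 and 123 bp. These correlations run across peaks, which are not independent replicates. The control used for each list is not given, so agreement that comes from a common control cannot be told apart from agreement of MCM signal. Pearson's r was 0.797 over the 5775 pairs with both scores at or below 20, a limit chosen after seeing the scores.

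**Figure D1:**
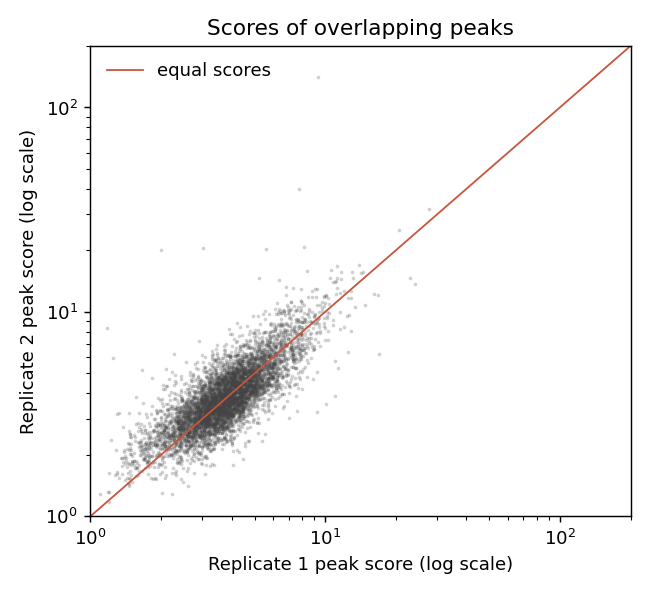
Scores of 5784 overlapping peak pairs, with the replicate 1 score on the x axis and the replicate 2 score on the y axis, both on log scales in the authors' score units. Each point is 1 pair and the line marks equal scores; points lie along the line, with a Spearman rho of 0.776.

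The next comparison asked which peaks were shared. In replicate 1, the share found in replicate 2 was 42.9% in the lowest quartile of scores and 59.2%, 70.6% and 66.7% in the following quartiles. In replicate 2, the shares were 50.9%, 79.2%, 81.9% and 69.0%. The relation was thus not monotonic, since the highest decile of replicate 2 scores was found in only 50.9% of cases (exact 95% interval 47.5 to 54.3), against 81.2% in the decile before it. Rank and recovery were still positively related over each list (rho = 0.192 in replicate 1 and 0.142 in replicate 2, permutation p = 1e-05 for each, the smallest possible, adjusted p = 1.6e-05). Recovery also rose with peak width, in a comparison added after the lists were examined. From the narrowest to the widest quartile, recovery was 18.1%, 48.2%, 80.9% and 92.1% in replicate 1 (rho = 0.597) and 38.1%, 66.8%, 87.0% and 89.2% in replicate 2 (rho = 0.428; p = 1e-05 for each). A wider peak also has more positions at which to meet another, so this relation holds an effect of length. Score and width were not separated. From the lowest to the highest score quartile, median widths were 89, 137, 165 and 148 bp in replicate 1. In replicate 2 they were 68, 100, 114 and 99 bp, so recovery by score may hold an effect of width.

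**Figure D2:**
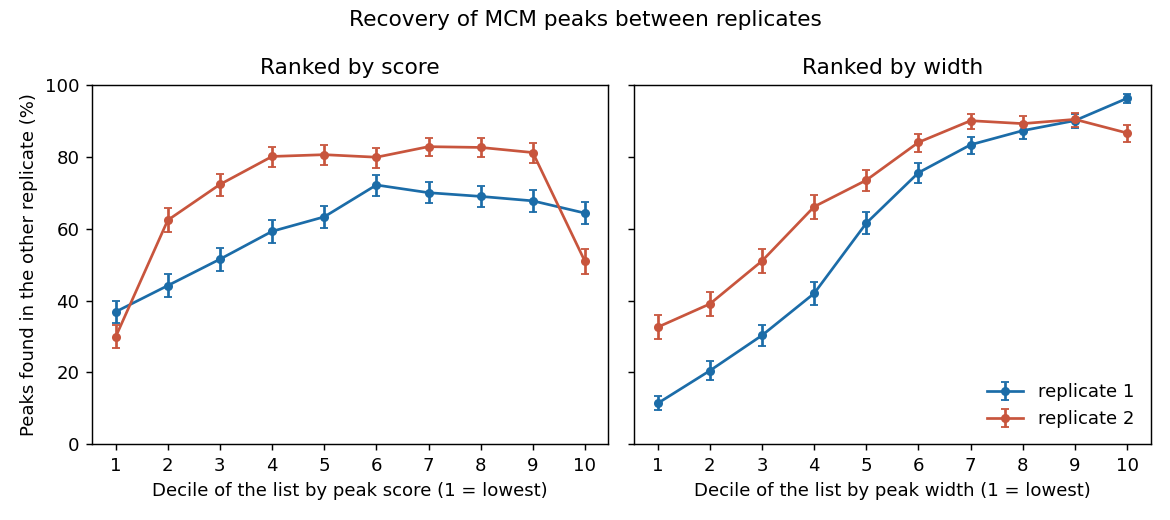
Percent of peaks of each replicate found in the other replicate (y axis), by decile of the list ranked by score (left) or by width (right), with decile 1 the lowest. Bars are exact binomial 95% intervals that cover counting error only; recovery fell to 50.9% in the highest score decile of replicate 2 and reached 96.3% in the widest decile of replicate 1.

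MCM peaks were spread over all major arms. In the series list the density was 44.2 peaks per Mb on 2L, 51.6 on 2R, 44.0 on 3L, 49.4 on 3R and 46.8 on X. Over the replicate lists the means were 65.3 ± 12.7 (SD, n = 2) on 2L, 77.4 ± 12.5 on 2R, 68.4 ± 6.86 on 3L, 73.5 ± 8.62 on 3R and 77.3 ± 4.42 on X. These SDs include the higher overall number of peaks in replicate 1. Within each replicate 2R was denser than 2L, with 86.2 and 74.2 peaks per Mb in replicate 1 and 68.5 and 56.3 in replicate 2, and differences among the arms were not tested. Chromosome 4 had 35.1 peaks per Mb in the series list and 81.3 ± 17.8 over the replicates. On the unplaced sequence U the series list had 1.79 peaks per Mb, while replicate 1 had 5.38 and replicate 2 had 29.0.

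S2-DRSC cells are male, and X was therefore compared with the autosome arms. X had 46.8 peaks per Mb and the autosome arms 47.3, a ratio of 0.989 (two-sided permutation test over 500 kb windows, p = 0.873, adjusted p = 0.873). The ratio was 1.16 in replicate 2 alone (permutation p = 0.0606) and 1.03 in replicate 1 alone (p = 0.634), and neither passed 0.05. Scores on X were slightly lower than on the autosome arms. The median score was 3.72 over 1048 X peaks and 3.81 over 4564 autosome peaks, with median score percentiles of 47.2 and 50.6 and a difference of -3.47 points (permutation p = 0.0413, adjusted p = 0.0472 over 8 tests). With replicate 2 alone the difference was -3.31 points (permutation p = 0.0155), and with replicate 1 alone it was -0.957 points and no longer passed the threshold (p = 0.465). Neighbouring peaks and windows are not independent, so these p-values are lower limits.

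Peaks occurred in clusters. In the series list, 77.8% of peaks had another peak within 10 kb, against 60.4% ± 0.712 (SD) in 10000 uniform placements of the same number of peaks per chromosome (permutation p = 1e-04, the smallest that the placements can give; adjusted p = 1.33e-04). The values were 87.3% against 78.2% in replicate 1 and 84.0% against 71.4% in replicate 2. In 598 windows of 200 kb the median was 9 peaks, the variance was 3.94 times the mean, and 20 windows held none. The densest window of the series list was 2L 0.4 to 0.6 Mb with 40 peaks (52 in replicate 1 and 56 in replicate 2). It was followed by 3R 12 to 12.2 Mb with 36 and 3L 10.6 to 10.8 Mb with 34. The order differed in replicate 2, with 70 peaks at 3L 10.6 to 10.8, 69 at 3L 3.4 to 3.6 and 67 at 3R 19 to 19.2 Mb. The placements ignored how uniquely reads can be placed in each part of the genome.

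**Figure D3:**
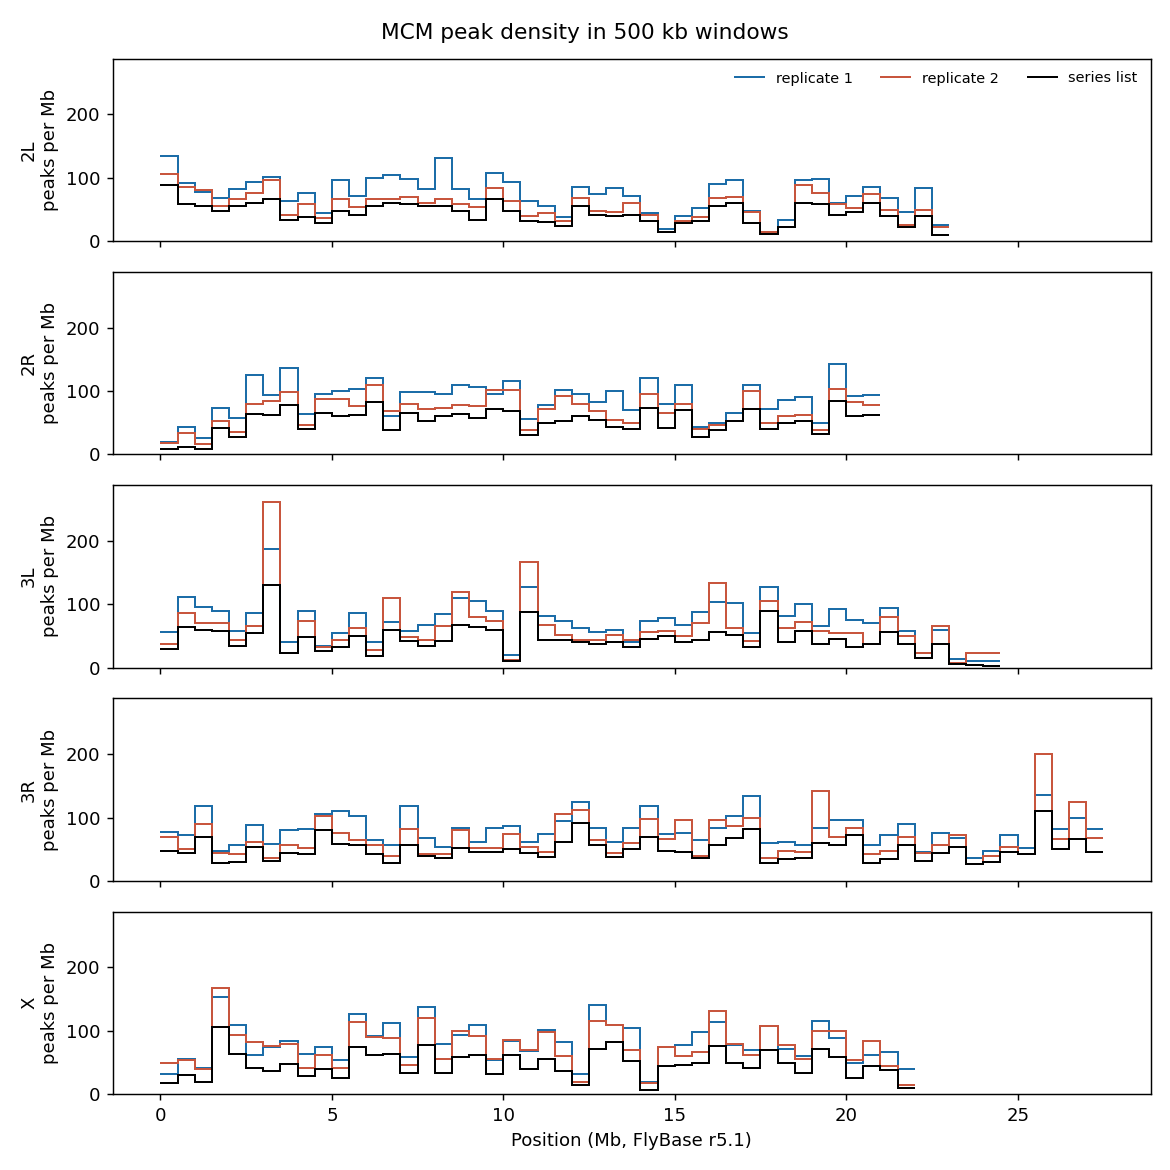
Peaks per Mb (y axis) in full 500 kb windows along the 5 major arms (x axis, position in Mb), for replicate 1, replicate 2 and the series list; partial windows at arm ends are not drawn. Density varied along every arm, around series list means of 44.0 to 51.6 peaks per Mb.

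Among the 20 series intervals with the highest scores, 5 were on X, 4 on 3L, 4 on chromosome 4, 3 on 2L, 2 on 2RHet, 1 on 3LHet and 1 on U, and none was on 2R or 3R. They were 28 to 360 bp wide as series intervals and scored 12.9 to 75.1. Some rested on much shorter replicate 2 peaks, of 1 bp in MCM_5406, 5 bp in MCM_4646 and 12 bp in MCM_4633. In 12 of the 20, the replicate scores were within 1.5 times each other. The highest, MCM_5713 at X 21834808 to 21835095, scored 75.1, which rested on replicate 2 (140.8, against 9.34 in replicate 1). MCM_2112 at 2RHet 198088 to 198115 scored 27.8 in replicate 1 and 31.8 in replicate 2, and MCM_5382 at X 14975223 to 14975288 scored 20.5 and 25.2. MCM_4673 at U 9143026 to 9143212 scored 7.72 and 39.9. On chromosome 4, MCM_4646 at 951278 to 951422 scored 24.2 and 13.7, MCM_4619 at 152660 to 152855 scored 22.9 and 14.6, and MCM_4626 at 214420 to 214580 scored 14.2 and 15.5. Positions are on FlyBase release 5.1. Gene content at these positions was not analysed here.

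The widest interval, MCM_1020 at 2LHet 248307 to 368107, was 119801 bp long and differed in width between the replicates. It came from 1 peak of 119730 bp in replicate 1, with a score of 1.18, and 1 peak of 101 bp in replicate 2, with a score of 8.32. The other 4 of the 5 widest lay in 2 regions. MCM_5275 (X 12622955 to 12635343, 12389 bp) and MCM_5263 (X 12565795 to 12571447, 5653 bp) were on X. MCM_2159 (3L 631820 to 642919, 11100 bp) and MCM_2161 (3L 648348 to 658426, 10079 bp) were on 3L. MCM_5275 was 1 peak in replicate 2 and 6 peaks in replicate 1, and MCM_2161 was 1 peak in each, with a series score of 1.20.

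**Figure D4:**
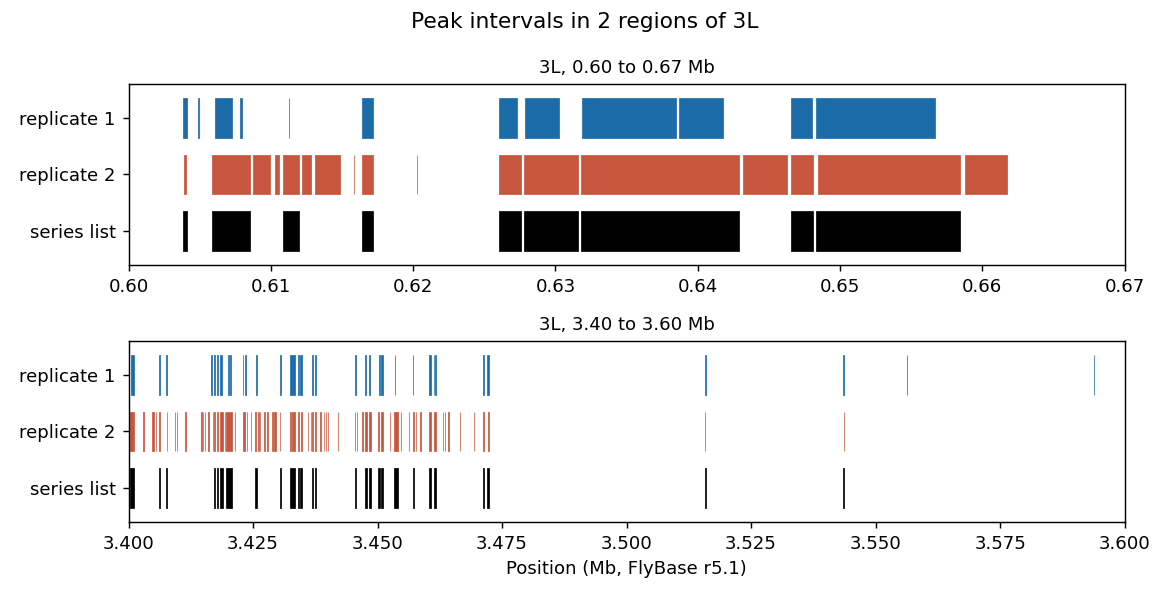
Peak intervals in replicate 1, replicate 2 and the series list (rows) along 2 regions of 3L (x axis, position in Mb), drawn to scale. The upper region holds MCM_2159 and MCM_2161, of 11100 and 10079 bp, and the lower region holds 34 replicate 1 and 69 replicate 2 peaks between 3.4 and 3.6 Mb.

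The 5 longest stretches without a series peak on the major arms were 589, 508, 447, 428 and 371 kb long. The longest, X 21245385 to 21834807, ended at the highest-scoring interval, and the mean density of X would give 27.6 series peaks in it. It held 6 replicate 1 and 2 replicate 2 peaks, for which 27.6 is not the expected number, since the replicate lists are denser. The 3 on 3L were at 24021622 to 24529170, 23573982 to 24021373 and 22281832 to 22710284. They held 4, 3 and 1 replicate 1 peaks and 9, 12 and 0 replicate 2 peaks, in that order. The stretch on 2R was at 2129918 to 2501119, with 5 and 1. All 5 stretches lay in or near the 2 Mb of their arm nearest the centromere. How uniquely reads can be placed there was not taken into account. The median distance between series peaks on the major arms was 7242 bp, and 49 distances exceeded 200 kb.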

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

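Apart from the score ratio of shared peaks in dense replicate 2 windows, the tests in this part were chosen after the results were seen. For the wide intervals, both tests given here replaced earlier ones whose results were already known. One earlier test compared the scores of the widest and narrowest quartiles (differences of 0.757 in replicate 1, 0.469 in replicate 2 and -0.274 in the series list). It is not used, because the widest quartile of the replicate lists had median widths of 347 and 274 bp. The other took the low score of the wide intervals as its own evidence. The conditions for excluding averaging in the wide intervals were also made stricter after the values were known. The bound for the width of high-scoring peaks was also restated, with an interval of the difference, after the median widths were known.

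Sequence outside the main comparisons carried peaks, with no control list to set them against. Replicate 1 had 54 and replicate 2 had 291 peaks on the unplaced sequence U, and the heterochromatin scaffolds held 140 and 218.

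Replicate 2 had 197 peaks with scores above 20, of which 89 exceeded 100 and 7 were found in replicate 1, while replicate 1 had 12 such peaks. Of the 197, 85.3% (exact 95% interval 79.5 to 89.9) lay off the 5 major arms, on U, heterochromatin scaffolds or chromosome 4. This compares with 5.22% (4.75 to 5.73) of the other 8250 (Fisher's exact test, p = 2.238e-170). Neighbouring peaks are not independent, so the p-value is a lower limit. Repeat-rich sequence is a candidate explanation, but repeats were not measured, and a place off the major arms is only a rough stand-in for them. A general rise of replicate 2 scores was argued against by a median ratio of 1.02 at paired peaks. The high-scoring peaks had a median width of 104 bp, against 96.5 bp in the others. The bootstrap 95% interval of the difference was 2 to 46.2 bp, but a permutation test found no difference (p = 0.178). High-scoring and other peaks also differ in where they lie, so these widths do not decide whether short intervals raise the score. How the score treats sequence with few control reads stays open, and no biological explanation was tested, since both samples belong to 1 group.

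Of the 2032 replicate 2 peaks on the major arms without a match, most lay elsewhere, but 4 windows of 200 kb held many of them, with 41 at 3L 3.4 to 3.6, 34 at 3L 10.6 to 10.8, 37 at 3L 16 to 16.2 and 39 at 3R 19 to 19.2 Mb. The highest count was 41, against a mean highest count of 21.3 when the unmatched labels were shuffled (permutation p = 1e-04, the smallest that 10000 shuffles can give). This argues against a random scatter of independent peaks. Neighbouring peaks are not independent, so the p-value is a lower limit. For replicate 1 the highest count was 19 (permutation p = 0.981). The replicate 2 peaks without a match had low median scores in the 4 windows, of 2.06, 2.48, 2.00 and 2.15 in that order. Over all such replicate 2 peaks on the autosome arms the median was 2.94. Shared peaks in these windows had a median log2 ratio of replicate 2 over replicate 1 of 0.24, against 0.03 elsewhere, a difference of 0.21 (window permutation p = 0.00573, higher in 4 of 4 windows). The rise was small (1.15 times), and the medians of the 4 windows ran from 0.149 to 0.335. The 5th to 95th percentiles of the other windows were -0.180 to 0.266, so the ranges overlapped. A local rise of replicate 2 signal may account for the extra peaks, as a hypothesis. A difference in DNA copy number and a difference in MCM occupancy stay open, because no read signal was used here.

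Wide intervals had low scores as a group, although the widest, MCM_1020, had a series score of 4.75. The 20 series intervals of at least 2 kb had a median score of 2.95, against 3.80 over the series list (permutation p = 0.0029 on score percentiles), and the wide peaks of replicate 1 and replicate 2 had median percentiles of 12.9 and 14.9. The highest percentiles among wide peaks were 80.8 in the series list, 86.9 in replicate 1 and 99.8 in replicate 2. Several wide intervals lay close together on 3L and on X, and neighbouring peaks are not independent. The p-values for wide intervals and for their neighbours are therefore lower limits. Averaging of a few strong short peaks over a broad interval stays open. In 11 intervals that were whole in 1 replicate and split in the other, the highest piece scored a median of 0.994 times the whole (range 0.720 to 1.23), but that piece was under 500 bp in only 3 of the 11, and in MCM_1020, with 1 peak per replicate, the peak of 101 bp scored 7.07 times the peak of 119730 bp. Many reads in the control DNA may lower these scores, but the test left this open: series peaks under 500 bp within 10 kb of a wide interval had a median percentile of 41.6 against 51.1 for all short peaks (permutation p = 0.217), while in replicate 1 (18.4, p = 1e-04, the smallest possible) and replicate 2 (32.8, p = 3e-04) they were lower, and no biological explanation was tested.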

How the results depend on the processing

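Tests of X density without dense windows, of log2 scores and of pairs at or below 20 were chosen after seeing the data. Replicate overlap, score agreement, recovery by score rank and clustering kept their direction and their side of 0.05 under every alternative run, and X density did not pass 0.05 in any, with a ratio that lay on both sides of 1 (0.924 to 1.16). Overlap ranged from 39.6% (at least 50% of the peak's length) to 67.8% (centres within 500 bp) for replicate 1 and from 63.4% to 77.3% for replicate 2. Intervals of the series list found in both replicates moved from 100% to 63.8% when at least 50% of the length had to be covered, to 99.8% with centres within 500 bp and to 88.1% in the higher-scoring 50% of each list. The stricter settings drop matches by construction. The lower score on X ranged from -3.31 to -0.957 points with 1 replicate left out, and lost its call without replicate 2. The cause was not tested. Restricting it to peaks found in both replicates removed no peak and shows nothing. Taking log2 scores cannot change a rank correlation, so that setting shows nothing for rho. Both settings are counted among the 31 values given next. Among these results 31 values stayed on their side of the threshold, 1 weakened and 3 moved, and no value that had passed its test reversed. Among single regions and added results, 1 weakened, and 11 densities per arm moved by more than 1 SD of the replicates, all of them upward from the shared list. The other 46 did neither, but for single peaks this was fixed in advance. Their series score is the mean of 2 replicate scores, and either score always lies within 1 SD of that mean. The count therefore shows nothing about how stable the score of a single peak is. The score of MCM_5713 was 140.8 without replicate 1 and 9.34 without replicate 2, that of MCM_4673 was 39.9 and 7.72, and that of MCM_4633 was 20.2 and 5.62. No paired analysis was possible because the immunoprecipitation and input groups share 1 replicate number and the input has no list analysed here. The alternatives on transcription start sites, genomic features, gene groups and base composition were not run. Depth is unknown, so its effect on peak number and on weak peaks cannot be given.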

Other observations

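All tests in this part were chosen after the lists were examined. MCM peaks were sparser near centromeres. In the 2 Mb of each major arm nearest its centromere the series list had 26.7 peaks per Mb, against 49.0 in the rest, a ratio of 0.546 (window permutation p = 2e-04, adjusted p = 3e-04 over 3 lists). The ratio was 0.611 in replicate 1 and 0.603 in replicate 2. Windows near a centromere form 1 stretch per arm and are not independent, so the p-value is a lower limit. How uniquely reads can be placed near centromeres was not taken into account. Per arm the series list ratios were 0.300 on 3L, 0.318 on 2R, 0.545 on X, 0.608 on 2L and 0.959 on 3R, and the difference among arms was not tested. On 3L the ratio was 0.328 in replicate 1 and 0.493 in replicate 2, and on 2R it was 0.451 and 0.413, so which arm was lowest depended on the replicate.

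Peaks on chromosome 4 had higher scores than those on the major arms in the series list, with a median of 5.11 over 46 peaks against 3.79, a difference of 31.3 percentile points (permutation p = 1e-04, the smallest possible, adjusted p = 1.5e-04 over 3 lists). In replicate 1 the medians were 5.54 and 3.55 (37.3 points, permutation p = 1e-04). In replicate 2 alone they were 3.89 and 3.63, a difference of 7.41 points that did not pass the threshold (permutation p = 0.156). The call therefore rests on replicate 1. Labels of single peaks were permuted and neighbouring peaks are not independent, so these p-values are lower limits.

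Replicate 2 peaks on X were found in replicate 1 less often than those on the autosome arms, in 65.5% against 76.4% of cases, a difference of -10.9 points (permutation of 500 kb windows, p = 1e-05, the smallest possible, adjusted p = 2e-05 over 2 lists). For replicate 1 peaks the shares were 59.2% and 61.0%, a difference of -1.72 points (permutation p = 0.258). Whether the replicates differ in this was not tested. Neighbouring windows are not independent, so these p-values are lower limits. The unmatched replicate 2 peaks had median widths of 37 bp on X and 36 bp on the autosome arms. Over all replicate 2 peaks, matched or not, the median width was 86 bp on X. It was 101 bp on 2L, 99 bp on 2R, 95 bp on 3L and 100 bp on 3R. Recovery rose with width, and whether width accounts for the lower share on X was not tested.

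High-scoring replicate 2 peaks also occurred at chromosome ends. Of those with scores above 20, 6 lay at X 6187 to 13938 and 7 at chromosome 4 1280722 to 1310391, where replicate 1 had 0 peaks. These bounds were taken from the replicate 2 peaks. Replicate 1 had 80.4 peaks per Mb on X and 93.9 on chromosome 4, so few or no peaks would be due in stretches this short. The count of 0 therefore shows no difference between the replicates. In 3 regions chosen because wide peaks lie there, the series list had, counting peaks of any width, 9 peaks between 603842 and 658426 on 3L, 26 between 12553332 and 12650036 on X, and 20 between 470331 and 499362 on 2L. Replicate 1 and replicate 2 had 12 and 17 peaks in the 3L region, where the last replicate 2 peak ended at 661758, 45 and 42 in the X region, and 24 and 25 in the 2L region.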
